A study of Mus musculus with 140 samples.

How the data were processed

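RNA was measured in kidneys of male C57BL6/OlaHsd wild-type mice by 3′ end sequencing with Lexogen QuantSeq libraries, a method that gives reads near the polyadenylated end of each transcript. Per the labels, arterioles, glomeruli, peritubular capillaries and post-capillary venules were taken by laser microdissection, and whole kidney was not microdissected. The labels name 7 groups of 4 mice, which are healthy mice at 0 h, and mice examined 4, 24 or 72 h after a sham operation or after cecal ligation and puncture (CLP), a surgical model of sepsis. Each of the 28 mice gave 5 libraries, 140 in all. The hours written in the count table differed from the labels for the 20 libraries of healthy mice, which the table puts at 4 h and the labels at 0 h, and the labels were used.

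The deposited table holds raw counts of reads per Ensembl gene, whole numbers for 34255 genes, with no normalisation by the authors. The labels name FastQC 0.11.8, MultiQC 1.7, STAR 2.7, SAMtools 1.9, HTSeq 0.13 and featureCounts, and the genome builds GRCm38.p6 and GRCm39. Which build the reads were aligned to, which program counted them, and whether duplicates were removed are not stated. Gene symbols came from the deposited table, and positions from GENCODE M21 (build GRCm38), in which 34185 of the genes were found by identifier. Library totals ran from 4.24 to 18.3 M counts (M for mega). A gene with no count in a library is bounded at 3 counts per library, and this floor covers counting error only, since reads without molecular identifiers are not independent molecules. Folds against a group with no counts divide the mean CPM of the other group by this floor. They are lower bounds for that mean under counting error alone. They bound neither single mice nor transcripts missed at capture.

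The data were analysed in R 4.3.3. Groups were compared with the quasi-likelihood F test of edgeR 4.0.16 (robust fit, TMM scaling, filterByExpr by group), which is two-sided, and genes with a Benjamini-Hochberg adjusted p under 0.05 passed. For CLP against sham in each compartment and at each time, and for sham at 4 h against healthy mice, the 28 libraries of a compartment were fitted together, with 4 mice in each group compared. Replicate numbers of different groups belong to different mice and were not used as a block. In whole kidney, residuals of CLP and sham libraries with the same number were nevertheless correlated above 0.1 in 3 of 4 pairs at 24 h (up to 0.52) and 2 of 4 at 72 h (up to 0.45). An order of processing is not given in the labels. Genes that distinguish a compartment were tested in the 16 microdissected libraries of the healthy mice, each compartment against the mean of the 3 others, with the mouse as a block. Whether the change with CLP differed between the 4 microdissected compartments was tested at each time by 3 interaction terms together, in the 32 libraries of 8 mice, with the mouse as a block. Fold changes are log2 values of the fit with their standard error (SE), and CPM values are counts per M counts of the TMM-scaled library total, as mean ± SD of 4 mice. The comparisons, tests, alternatives, gene lists and rule for naming genes were fixed before the data were examined, except where the text says otherwise.

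The 29 fixed gene lists covered coagulation (procoagulant, anticoagulant, fibrinolysis), inflammation (leukocyte adhesion molecules, NF-kB response, cytokines and chemokines, interferon response, acute-phase and complement), tubular injury, endothelial barrier, endothelial glycocalyx, immediate early genes, glucocorticoid targets, circadian clock, cell cycle, mitochondrial respiration, and markers of 13 kinds of kidney, vessel or blood cell. They were tested with camera in limma 3.58.1 on voom values (preset correlation 0.01), with estimated correlation and the directional test of fry beside it. Lists with fewer than 3 measured members were not tested, and p was adjusted over the 423 tests of the 15 CLP comparisons. Members that passed when p was adjusted over the list alone are counted beside those that passed over all genes. The lists of PPAR-alpha targets and of MHC class II genes were written after the genes had been seen to move. Counts of the 4 microdissected libraries of each mouse were also summed and fitted as a comparison added after the data had been seen, with 87 list tests adjusted as a family of their own. This sum of raw counts weights each compartment by its depth.

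Genes were named by rule. At each time the 8 highest and 8 lowest genes called in at least 3 microdissected compartments were to be taken, and since too few were, those called in at least 1 compartment. Each CLP comparison gave its 3 highest and 3 lowest passing genes with a mean of at least 5 CPM and CLP and sham values that did not overlap. Up to 4 members of each fixed list were taken per comparison, and any member of the coagulation lists, adhesion molecules, cytokines and NF-kB list. The 10 smallest adjusted p of each interaction test, and marker list members and the 5 highest genes of each compartment, completed the rule. Predicted genes (Gm and Rik symbols), mitochondrial, ribosomal protein and haemoglobin genes were left out of the first, second and interaction parts. Some genes that the rule named are not reported here.

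The alternatives tried were DESeq2 1.42.0 (its Wald or likelihood ratio test), DESeq2 size factors in edgeR, no filter on low counts, only the 8 libraries compared, these 8 with the replicate number as a block, no mouse block, and each library left out in turn. For compartment genes, the interaction and the summed counts, each mouse was left out in turn instead, with all its microdissected libraries. Added after seeing the data were fits to the mice of 1 block only (healthy and 4 h mice, or 24 and 72 h mice), genes with a mean of at least 100 CPM only, and the interaction and summed counts without peritubular capillaries. The fits were also tested on simulated data, in which 100 genes were changed by a known fold.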

Results

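Kidneys of 28 mice were profiled to follow genes of coagulation and inflammation in the renal microvasculature during sepsis. In each mouse RNA was read from 4 microdissected compartments (arterioles, glomeruli, peritubular capillaries and post-capillary venules) and from whole kidney, which gave 140 libraries with 4.24 to 18.3 M counts. Each of the 7 groups (healthy, and sham or CLP at 4, 24 and 72 h) held 4 mice, so every value for a group has n = 4. Microdissected libraries of the mice examined at 24 and 72 h held fewer detected genes than those of the healthy and 4 h mice, with medians of 8081 against 12611.5 in arterioles, 11717 against 13800.5 in glomeruli, 6982 against 12632.5 in peritubular capillaries and 10788.5 against 12876.5 in venules. In whole kidney these medians were 18311 and 19396.5. Peritubular capillary libraries of CLP mice at 72 h detected 3961 ± 1178 genes (SD), against 8239 ± 1158 in sham mice at 72 h. The biological coefficient of variation fitted over the 28 libraries was 1.92 in arterioles, 1.40 in glomeruli, 1.94 in peritubular capillaries, 1.58 in venules and 0.241 in whole kidney.

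**Figure D1:**
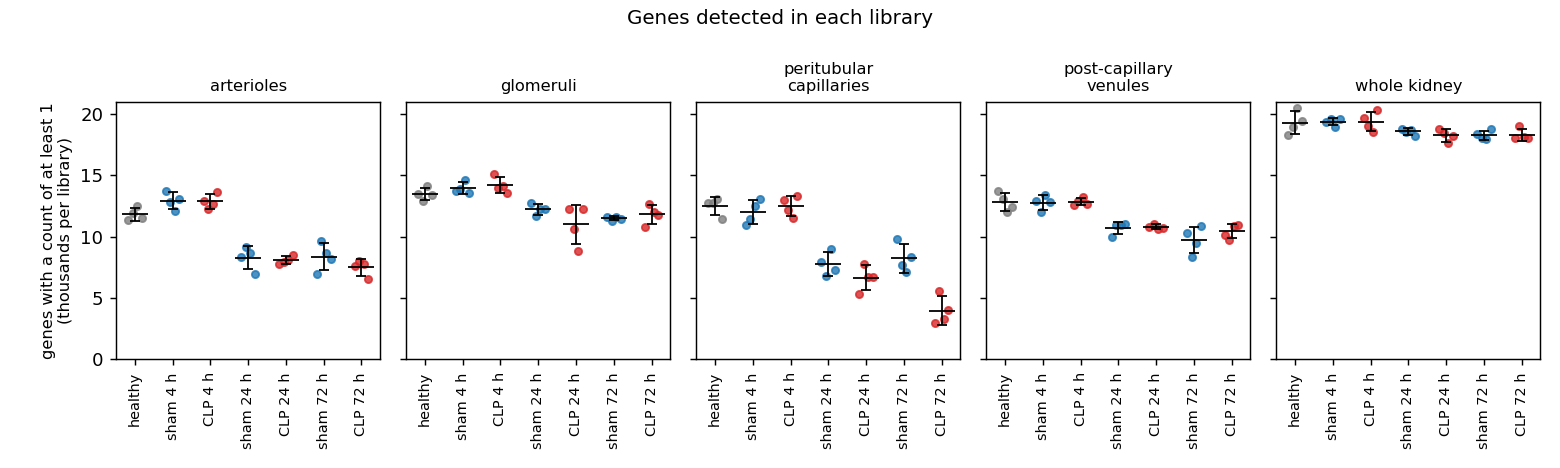
Genes detected in each library (vertical axis, number of genes) by group (horizontal axis) in 5 panels, 1 per compartment, with a point per library and the mean ± SD of 4 mice. Peritubular capillary libraries of CLP mice at 72 h lie between 2949 and 5595 genes, and those of sham mice at 72 h between 7137 and 9816.

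The first question was which transcripts mark each microdissected compartment in healthy kidney. Arterioles were rich in smooth muscle and endothelial transcripts. Acta2 (ENSMUSG00000035783, chromosome 19, 34241090 to 34255590), the actin of smooth muscle, had 12260 ± 5721 CPM in arterioles, a log2 fold change of 6.33 ± 0.21 over the mean of the 3 other compartments (adjusted p = 4.1e-35). Myh11, the smooth muscle myosin heavy chain, was higher by 6.34 ± 0.36, Vwf, the von Willebrand factor of endothelium and platelets, by 7.45 ± 0.71, and Pecam1, an endothelial adhesion molecule, by 3.37 ± 0.35. Of the measured markers, 10 of 13 for smooth muscle and renin cells were higher, as were 8 of 12 for arterial endothelium, 8 of 15 for all endothelium and 7 of 10 for fibroblasts, among them Mgp at 3.92 ± 0.22 and Dcn at 3.76 ± 0.33. Markers of proximal tubule were lower for 10 of 18. In all, 601 genes were higher and 290 lower of 12179 tested.

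Glomeruli were marked by podocyte genes. Nphs1 (ENSMUSG00000006649, chromosome 7, 30458315 to 30487223), nephrin of the slit diaphragm, had 262 ± 274.7 CPM and was higher by 8 ± 0.97 (adjusted p = 8.88e-09). Wt1, a transcription factor of podocytes, was higher by 7.03 ± 0.85, Kdr, a VEGF receptor of endothelium, by 3.48 ± 0.50, and Ren1, renin, by 5.49 ± 0.67. Markers were higher for 15 of 16 of podocytes and 9 of 13 of glomerular endothelium and mesangium, and lower for 13 of 18 of proximal tubule, with Kap at −2.41 and Slc34a1 at −1.66. Ehd3, expressed by glomerular endothelium, was higher by 4.22 ± 0.66, a call lost without healthy replicate 4 (adjusted p = 0.0594). The count was 341 higher and 168 lower genes, 509 together, and 321 without healthy replicate 3 or 323 without healthy replicate 4.

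Peritubular capillary libraries were dominated by transcripts of proximal tubule. Kap (ENSMUSG00000032758, chromosome 6, 133849851 to 133853762), an androgen-regulated protein of the proximal tubule, had 67500 ± 17050 CPM there and was higher by 3.13 ± 0.13 (adjusted p = 1.84e-28). Slc34a1, a phosphate transporter, was higher by 2.25 ± 0.21, Lrp2, the endocytic receptor megalin, by 2.46 ± 0.33, and 15 of 18 proximal tubule markers were higher. Of 15 markers of all endothelium 5 were lower, with Pecam1 at −2.70 ± 0.45, and Kdr, at 0.07 ± 0.57 (adjusted p = 0.974), did not pass. Cd36, a fatty acid transporter of capillary endothelium, was higher by 4.20 ± 0.65. Of 9 measured markers of peritubular capillary and venous endothelium, however, 1 was higher, 1 lower and 7 did not pass. Smooth muscle markers were lower for 7 of 13 (Acta2 −4.31 ± 0.29), fibroblast markers for 6 of 10 and erythrocyte and platelet markers for 5 of 9 (Hbb-bt −4.88 ± 0.38). The count was 429 higher and 318 lower genes, 747 together, and 455 without healthy replicate 3.

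Post-capillary venules stood out less from the other 3 compartments. Dcn (ENSMUSG00000019929, chromosome 10, 97479609 to 97518143), the proteoglycan decorin of fibroblasts, was higher by 2.93 ± 0.33 (adjusted p = 4.87e-09), Mgp, a matrix protein of vessel walls, by 1.22 ± 0.22, and Hbb-bt, adult beta globin, by 2.36 ± 0.25. Markers were higher for 3 of 10 of fibroblasts, 4 of 9 of erythrocytes and platelets and 3 of 18 of proximal tubule, with Acsm2 at 1.04 ± 0.20. Vwf (1.07, adjusted p = 0.733) and Pecam1 (−1.33, adjusted p = 0.14) did not pass. Of 9 measured markers of peritubular capillary and venous endothelium, 0 were higher and 0 lower in venules. The count was 45 higher and 27 lower genes, 72 together, and 35, 42, 43 and 44 without healthy replicates 1, 2, 3 and 4.

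The main question was how CLP changed each compartment against a sham operation. In whole kidney at 4 h, chemokines, adhesion molecules and targets of NF-kB rose. Cxcl1 (ENSMUSG00000029380, chromosome 5, 90891241 to 90893115), a chemokine that attracts neutrophils, rose by 4.95 ± 0.44 (adjusted p = 6.78e-08), from 2.83 to 87.2 CPM. Icam1 (ENSMUSG00000037405, chromosome 9, 21015985 to 21028817), an endothelial ligand of leukocyte integrins, rose by 2.50 ± 0.27 (adjusted p = 1.54e-06), Selp, P-selectin, by 3.97 ± 0.69, and Nfkbia, the inhibitor of NF-kB, by 1.40 ± 0.16. Il1b, an inflammatory cytokine, rose by 2.69 ± 0.42, Saa3, an acute-phase protein, by 5.34 ± 0.79, and Fpr2, a receptor of neutrophils for formyl peptides, by 5.31 ± 0.50. Among coagulation genes, Thbd (ENSMUSG00000074743, chromosome 2, 148404466 to 148408188), the thrombin receptor thrombomodulin, rose by 0.92 ± 0.19 (adjusted p = 0.00334). Fga, a fibrinogen chain, passed at 1.78 ± 0.45 (adjusted p = 0.0369), and the call was lost without sham replicates 1, 2, 3 or 4 or CLP replicates 1 or 2, with adjusted p up to 0.186 without CLP replicate 1. Thbs1, thrombospondin, passed at 1.02 ± 0.27 and lost the call without those same 6 libraries, with adjusted p up to 0.29. Vcam1, an adhesion molecule of activated endothelium, passed at 0.95 ± 0.21, lost without sham replicate 2 or CLP replicate 1 (adjusted p up to 0.12).

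Lower in whole kidney at 4 h were Adamts5, a matrix protease, at −1.57 ± 0.28, Rasgrp2 at −1.39 ± 0.20, Igf2bp1 at −1.42 ± 0.24, and the endothelial genes Ehd3 at −0.82 ± 0.18 and Nr2f2, a transcription factor of venous endothelium, at −0.58 ± 0.12. Kdr, at −0.62 ± 0.14 (adjusted p = 0.00688), lost the call without CLP replicate 1 (adjusted p = 0.052). Of 14936 genes 252 were higher and 83 lower, 335 together, and 206 without sham replicate 2, 214 without sham replicate 3 or 213 without CLP replicate 1.

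In glomeruli at 4 h, 13 genes rose and 3 fell of 14586. Mt1 (ENSMUSG00000031765, chromosome 8, 94179082 to 94180327), a metallothionein that binds zinc, rose by 3.45 ± 0.30 (adjusted p = 9.66e-11), from 963.5 to 10510 CPM. Ngp (ENSMUSG00000032484, chromosome 9, 110419747 to 110423012), a granule protein of neutrophils, had 97.9 ± 42 CPM in CLP mice and 0.159 ± 0.185 in sham mice, where 2 of 4 libraries held any count (adjusted p = 0.00208). Sele (ENSMUSG00000026582, chromosome 1, 164048234 to 164057677), E-selectin of activated endothelium, had 123 ± 39.3 CPM in CLP mice and 0.0631 ± 0.0734 in sham mice, where 2 of 4 libraries held any count (adjusted p = 0.0318). The call of Sele was lost without any of the 4 sham mice or CLP replicates 1 or 4, with adjusted p up to 0.217 without sham replicate 1. Ier3, an early response gene, rose by 2.38 ± 0.43, lost without sham replicate 1 (adjusted p = 0.0724), and the transcription factor Junb by 2.78 ± 0.61, lost without any of the 4 sham mice or CLP replicates 1, 3 or 4 (adjusted p up to 0.314). The fallen genes were Chst1, Tbxa2r and Gm28730, the last named after its values were seen. Chst1 fell by 2.02 ± 0.43 and lost the call without sham replicates 1, 2 or 3 or CLP replicates 1, 2 or 4 (adjusted p up to 0.219), and Tbxa2r, the thromboxane receptor, had 0.297 CPM in CLP and 28.8 in sham mice and lost it without sham replicates 1 or 2 or CLP replicates 1, 2 or 4 (up to 0.187). Gm28730 fell by 2.42 ± 0.53 (adjusted p = 0.0376) and lost it without sham replicates 1, 2 or 3 or any of the 4 CLP mice (up to 0.35). Thbd at 1.79 (adjusted p = 0.559) did not pass, though CLP mice had 611 ± 105 CPM (511 to 758) and sham mice 176 ± 59 (100 to 236). In simulated data 12 of 100 genes changed 4-fold were recovered in glomeruli at 4 h, so a missing call is no sign of no change. The 16 genes became 4, 6 and 6 without sham replicates 1, 2 and 3, and 5 and 8 without CLP replicates 1 and 4, and 10 of the 16 were called in whole kidney in the same direction. More genes than 16 passed with DESeq2, with edgeR fitted to the 8 libraries alone, and with edgeR fitted to the mice of the same block.

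In the other compartments at 4 h few single genes passed. Gm13889, a predicted gene named after its values were seen, was the 1 gene called in arterioles, higher by 3.32 ± 0.54 (adjusted p = 0.00144, 2771 against 276.4 CPM), and without sham replicate 3 there were 2. In peritubular capillaries 0 of 11772 genes passed in edgeR (384 had an unadjusted p under 0.05, and DESeq2 called 85). In venules 0 of 13530 passed in edgeR (768 had an unadjusted p under 0.05, and DESeq2 called 357), 1 without CLP replicate 1 and 2 without CLP replicate 4. When the 4 compartments of each mouse were summed, 14 genes were higher of 16834, with Mt1 at 2.99 ± 0.47, Junb at 2.77 ± 0.52, Cxcl1 at 7.39 ± 1.43 and Vcam1 at 2.06 ± 0.40. Mt1 lost the call without sham replicates 2 or 3 (adjusted p up to 0.0523), Junb without sham replicates 1 or 2 or CLP replicates 1 or 3 (up to 0.106), and Cxcl1 and Vcam1 without any of the 4 sham mice or CLP replicate 1 (up to 0.322 and 0.488). The summed count was 4, 4, 5 and 6 without sham replicates 1, 2, 3 and 4, and 3 and 9 without CLP replicates 1 and 2.

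As groups, inflammatory genes rose at 4 h in several compartments. The NF-kB list rose in whole kidney, where 13 of 18 members were higher (16 adjusted over the list alone) with a median of 1.53 (adjusted p = 1.5e-29), in glomeruli, with 2 higher (6 adjusted over the list alone) and a median of 2.22 (adjusted p = 2e-17), in venules with a median of 1.98 (adjusted p = 9.2e-10), and in arterioles with a median of 1.69 (adjusted p = 5.3e-09). These calls held with an estimated correlation. Cytokines and chemokines rose in whole kidney (10 of 20 higher, adjusted p = 1.1e-13), in glomeruli (15 of 17 with a positive fold change, adjusted p = 9.1e-09) and in peritubular capillaries (6 of 8 positive, adjusted p = 0.0019). The rises of this list in venules (adjusted p = 4e-04) and arterioles (0.018) were lost with an estimated correlation (adjusted p = 0.11 and 0.055). Leukocyte adhesion molecules rose in whole kidney (5 of 12 higher, 6 adjusted over the list alone, adjusted p = 2.4e-06) and glomeruli (1 of 12 higher, 3 adjusted over the list alone, adjusted p = 0.00011), and in venules at an adjusted p of 0.049, lost with an estimated correlation (adjusted p = 0.19). Neutrophil markers rose in glomeruli (14 of 14 positive, 1 higher, 10 adjusted over the list alone, adjusted p = 4.7e-19), venules (6 of 6 positive, adjusted p = 3.3e-08) and whole kidney (6 of 10 higher, adjusted p = 2e-15). Interferon response genes rose in whole kidney (8 of 21 higher, adjusted p = 3.1e-15), glomeruli (2e-06) and venules (0.0028), and in arterioles (0.0045) and peritubular capillaries (0.014) without holding with an estimated correlation (adjusted p = 0.16 and 0.074).

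Immediate early genes rose at 4 h in whole kidney (7 of 13 higher, adjusted p = 1.6e-15), glomeruli (1.2e-06), arterioles (0.00022) and venules (0.0074), and in peritubular capillaries at 0.011, lost with an estimated correlation (adjusted p = 0.095). In whole kidney Dusp1, a phosphatase of MAP kinases, rose by 1.52 ± 0.22 and Jun by 1.36 ± 0.22. Glucocorticoid targets rose in whole kidney (3 of 10 higher, adjusted p = 8.6e-12), arterioles (3.2e-09) and peritubular capillaries (0.0035), and in glomeruli (0.0083) and venules (0.0064), where the call was lost with an estimated correlation (adjusted p = 0.22 and 0.14). The members that passed in whole kidney included Mt1 at 1.64 ± 0.26 and Mt2 at 2.33 ± 0.26, which metals and inflammation also induce. Fibrinolysis genes rose in whole kidney at an adjusted p of 0.049 (2 of 10 higher), lost with an estimated correlation (adjusted p = 0.12), and procoagulant genes rose in peritubular capillaries at 0.037 (adjusted p = 0.23 with an estimated correlation). Arterial endothelium markers fell in glomeruli (0.029) and venules (0.021), and fibroblast markers rose in arterioles (0.047), calls lost with an estimated correlation (adjusted p = 0.25, 0.19 and 0.27).

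In whole kidney at 24 h, chains of fibrinogen and acute-phase genes rose. Fgg (ENSMUSG00000033860, chromosome 3, 83007724 to 83015049), the gamma chain of fibrinogen, rose by 6.10 ± 0.72 (adjusted p = 6.96e-06), from 8.53 to 587 CPM, Fga by 4.76 ± 0.51 and Fgb by 6.36 ± 0.84. Saa3 (ENSMUSG00000040026, chromosome 7, 46711998 to 46715700) rose by 9.62 ± 0.87 (adjusted p = 2.3e-07), Saa1, a related serum amyloid A, was at least 1320-fold higher, and Lcn2, lipocalin 2 of injured tubules and neutrophils, rose by 6.43 ± 0.74. Other coagulation genes that rose were F13a1, the subunit of the fibrin crosslinking factor XIII, by 1.77 ± 0.39, Entpd1, an ectonucleotidase that limits platelet activation, by 1.63 ± 0.34, and S100a10, part of a plasminogen receptor, by 0.93 ± 0.14, while Serpinf2, the inhibitor of plasmin, fell by 1.33 ± 0.17. Serpine2, a protease inhibitor, passed at 0.90 ± 0.26 and lost the call without any of the 4 sham mice or CLP replicates 2 or 4 (adjusted p up to 0.291). F3, tissue factor, was at 1.12 ± 0.99 and did not pass (adjusted p = 0.661).

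In whole kidney at 24 h 6 of 18 proximal tubule markers fell. The list lost its call with an estimated correlation (adjusted p = 0.11). Slc34a1 (ENSMUSG00000021490, chromosome 13, 55398187 to 55415592) fell by 0.99 ± 0.16 (adjusted p = 0.000113), Slc7a13, an amino acid transporter, by 2.68 ± 0.30, Miox, an enzyme of inositol breakdown, by 1.28 ± 0.18 and Kap by 0.73 ± 0.12. The genes of lowest fold change were Mgl2, a lectin of macrophages and dendritic cells, at −3.49 ± 0.44, Kif20b at −3.13 ± 0.38 and Mfsd2a, a lipid transporter, at −2.96 ± 0.54. Of 13 measured genes of tubular injury 6 rose, with Spp1, osteopontin, at 1.92 ± 0.30 and Timp1, an inhibitor of metalloproteases, at 3.28 ± 0.52. The call of this list was lost with an estimated correlation (adjusted p = 0.12). Icam1 rose by 1.36 ± 0.27, Cxcl1 by 2.62 ± 0.60, Il1b by 2.03 ± 0.41 and S100a8, a calcium-binding protein of neutrophils, by 4.13 ± 0.39. Of 14936 genes 454 were higher and 335 lower. With edgeR 462 passed when the 8 libraries alone were fitted with the replicate number as a block (295 without the block).

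In glomeruli at 24 h, 14 genes rose and 6 fell. Nupr1 (ENSMUSG00000030717, chromosome 7, 126623249 to 126630861), a stress-induced chromatin protein, rose by 2.47 ± 0.36 (adjusted p = 0.000186), Cp, the copper carrier ceruloplasmin, by 2.19 ± 0.40 (adjusted p = 0.00432), and Ngp, counted in 3 of 4 CLP mice, was at least 82.7-fold higher (adjusted p = 0.00188). Sele, counted in 3 of 4 CLP mice and in 0 of 4 sham mice, was at least 256-fold higher (adjusted p = 0.0112), a call lost without sham replicates 1, 3 or 4 (adjusted p up to 0.071). Saa3 was at least 418-fold higher, lost without any of the 4 sham mice or CLP replicates 2, 3 or 4 (up to 0.172), and C3, the central complement protein, rose by 2.36 ± 0.47, lost without sham replicates 1, 3 or 4 or CLP replicate 2 (up to 0.0946). Lrp2 fell by 2.06 ± 0.45, lost without sham replicates 1, 2 or 4 or CLP replicates 3 or 4 (up to 0.209). The 20 genes became 10, 13, 10 and 10 without sham replicates 1, 2, 3 and 4, 11 without CLP replicate 2 and 67 without CLP replicate 1, and 12 of the 20 were called in whole kidney in the same direction. Fitted to the 8 libraries alone, without or with the replicate number as a block, edgeR called under 10 genes. Fitted to the mice of the same block it also called under 10, so most of the 20 calls were lost each time.

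In the tubule-rich peritubular capillary libraries, 4 genes rose and 2 fell at 24 h. Slc34a1 fell by 1.46 ± 0.26 (adjusted p = 0.000527), from 7172 to 2599 CPM. Fgg had 460 ± 425 CPM in CLP mice and 0.119 ± 0.238 in sham mice, where 1 of 4 libraries held any count (adjusted p = 0.0425). Saa1 was at least 1390-fold higher (adjusted p = 0.0241), and the mean of Lcn2, counted in 3 of 4 CLP mice, at least 891-fold (adjusted p = 0.0448). The mean of Malsu1 was at least 455-fold higher (adjusted p = 0.0425), carried by the 2 of 4 CLP mice that held counts. Gm22748, named after its values were seen, fell by 3.74 ± 0.70. The call of Fgg was lost without sham replicates 1, 3 or 4 or CLP replicates 2 or 4 (adjusted p up to 0.167), those of Saa1 and Lcn2 without any of the 4 sham mice or CLP replicates 2 or 4 (up to 0.152 and 0.167), and that of Malsu1 without any of the 4 sham mice or CLP replicate 1 (up to 0.177). The 6 genes became 2, 3, 2 and 2 without sham replicates 1, 2, 3 and 4, and 11 without CLP replicate 3.

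In venules at 24 h, 3 genes rose and 8 fell, several of them genes of the proximal tubule. Slc34a1 fell by 1.27 ± 0.18 (adjusted p = 5.91e-06), Acy3 (ENSMUSG00000024866, chromosome 19, 3986570 to 3990007), an aminoacylase, by 1.97 ± 0.25 (adjusted p = 1.83e-07) and Akr1c21, a steroid dehydrogenase, was at −2.34 ± 0.29 (adjusted p = 1.83e-07). Saa3 was at least 1210-fold higher (adjusted p = 0.00557), lost without sham replicates 1, 2 or 3 (adjusted p up to 0.0655). Spp1 rose by 1.76 ± 0.38, lost without any of the 4 sham mice or CLP replicates 2 or 4 (up to 0.208), and Mt2 by 2.32 ± 0.46, lost without any of the 4 sham mice or CLP replicates 2, 3 or 4 (up to 0.242). The 11 genes became 4, 6 and 4 without sham replicates 1, 2 and 3, and 5 without CLP replicates 2 or 3, and 10 of the 11 were called in whole kidney in the same direction.

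In arterioles at 24 h, 2 genes fell of 12183. Rcn1, a calcium-binding protein of the endoplasmic reticulum, was at least 622-fold lower, at 0 CPM in CLP mice and 145.8 ± 78.4 in sham mice (adjusted p = 2.76e-05). Nat8f1, an acetyltransferase, had 0.0165 ± 0.0329 CPM in CLP mice, where 1 of 4 libraries held any count, and 129.5 ± 85.99 in sham mice (adjusted p = 0.00606), a call lost without CLP replicate 2 (adjusted p = 0.0671). The 2 genes became 6 without sham replicate 2, and 7, 1, 4 and 7 without CLP replicates 1, 2, 3 and 4. Fitted to the 8 libraries alone edgeR called 0 genes, and Rcn1 lost its call (adjusted p = 0.0685) as Nat8f1 did. DESeq2 called 1522 genes (1890 had an unadjusted p under 0.05 in edgeR). In the summed compartments at 24 h, 40 genes rose and 51 fell, 64 of the 91 also called in whole kidney in the same direction. Arteriole libraries held 10.46 to 13.73 M counts in CLP mice and 6.48 to 10.04 M in sham mice. Changes in the sum may therefore include a changed mix of compartments. C3 rose by 2.44 ± 0.37 (adjusted p = 0.000127), Slc34a1 fell by 1.58 ± 0.22 (adjusted p = 2.75e-05) and Miox by 1.59 ± 0.24, Cxcl1 was at least 401-fold higher, and Sele, counted in 3 of 4 CLP mice, at least 375-fold higher. The 91 genes became 45, 60 and 50 without sham replicates 1, 2 and 4, and 48 without CLP replicate 4.

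The acute-phase and complement list rose at 24 h in each of the 5 compartments, with positive fold changes for 15 of 16 members in arterioles (adjusted p = 8.3e-15), 14 of 14 in glomeruli (1.8e-14), 10 of 13 in peritubular capillaries (3.1e-12), 14 of 15 in venules (7.3e-12) and 18 of 18 in whole kidney (2e-22). Adjusted over the list alone, 6, 8, 8, 7 and 17 members were higher in that order, and the calls held with an estimated correlation. The list also rose at 4 and 72 h in each of the 5 compartments. At 4 h it held with an estimated correlation in arterioles, glomeruli and venules and not in peritubular capillaries (adjusted p = 0.16) or whole kidney (0.11), and at 72 h in arterioles, glomeruli and whole kidney and not in peritubular capillaries (0.11) or venules (0.1). Procoagulant genes rose at 24 h in peritubular capillaries (1 of 9 higher, 4 adjusted over the list alone, adjusted p = 0.015), venules (0.042) and whole kidney (4 of 15 higher, median 1.05, adjusted p = 0.0028), and none of these calls held with an estimated correlation (adjusted p = 0.17, 0.094 and 0.055). Anticoagulant genes rose in whole kidney (1 of 9 higher, 4 adjusted over the list alone, median 0.62, adjusted p = 0.0079), which held with an estimated correlation. Fibrinolysis genes rose in peritubular capillaries at an adjusted p of 0.0097, lost with an estimated correlation (adjusted p = 0.054). The higher members of the procoagulant list in whole kidney were the fibrinogen chains and F13a1.

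Leukocyte adhesion molecules rose at 24 h in glomeruli (1 of 12 higher, 4 adjusted over the list alone, adjusted p = 2.6e-07), and in whole kidney at 0.004 and, at 72 h, 0.036, lost with an estimated correlation (adjusted p = 0.17 and 0.32). Cytokines and chemokines rose in whole kidney (10 of 20 higher, adjusted p = 1.2e-06), and in glomeruli at 0.00015 (adjusted p = 0.065 with an estimated correlation). The NF-kB list in whole kidney at 24 h (adjusted p = 0.013) and 72 h (0.024), and the interferon list at 24 h (0.0037), were lost with an estimated correlation (adjusted p = 0.41, 0.46 and 0.49). Tubular injury genes rose in peritubular capillaries (adjusted p = 0.0011), and in venules (0.037) and whole kidney (4.1e-05), where the call was lost with an estimated correlation (adjusted p = 0.17 and 0.12), as it was in whole kidney at 72 h (0.0071, and 0.32 with an estimated correlation). Glucocorticoid targets rose at 24 h in whole kidney (6 of 10 higher, adjusted p = 1.4e-10), with Fkbp5 at 1.24 ± 0.24, and peritubular capillaries (0.00036), and in arterioles (0.014), glomeruli (0.002) and venules (0.023) without holding with an estimated correlation (adjusted p = 0.23, 0.14 and 0.21). Proximal tubule markers fell at 24 h in each of the 5 compartments, with medians of −1.91 in arterioles, −1.35 in glomeruli, −0.78 in peritubular capillaries, −0.84 in venules and −0.36 in whole kidney (adjusted p = 1e-06, 3.5e-07, 0.00032, 0.00056 and 5.4e-09). With an estimated correlation the fall held in venules (adjusted p = 0.04) and not in the others (adjusted p = 0.19, 0.19, 0.092 and 0.11). Markers of the loop of Henle, distal tubule and collecting duct fell in arterioles (0.00055), glomeruli (5.6e-05) and whole kidney (0.013), all lost with an estimated correlation (adjusted p = 0.18, 0.17 and 0.17).

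**Figure D2:**
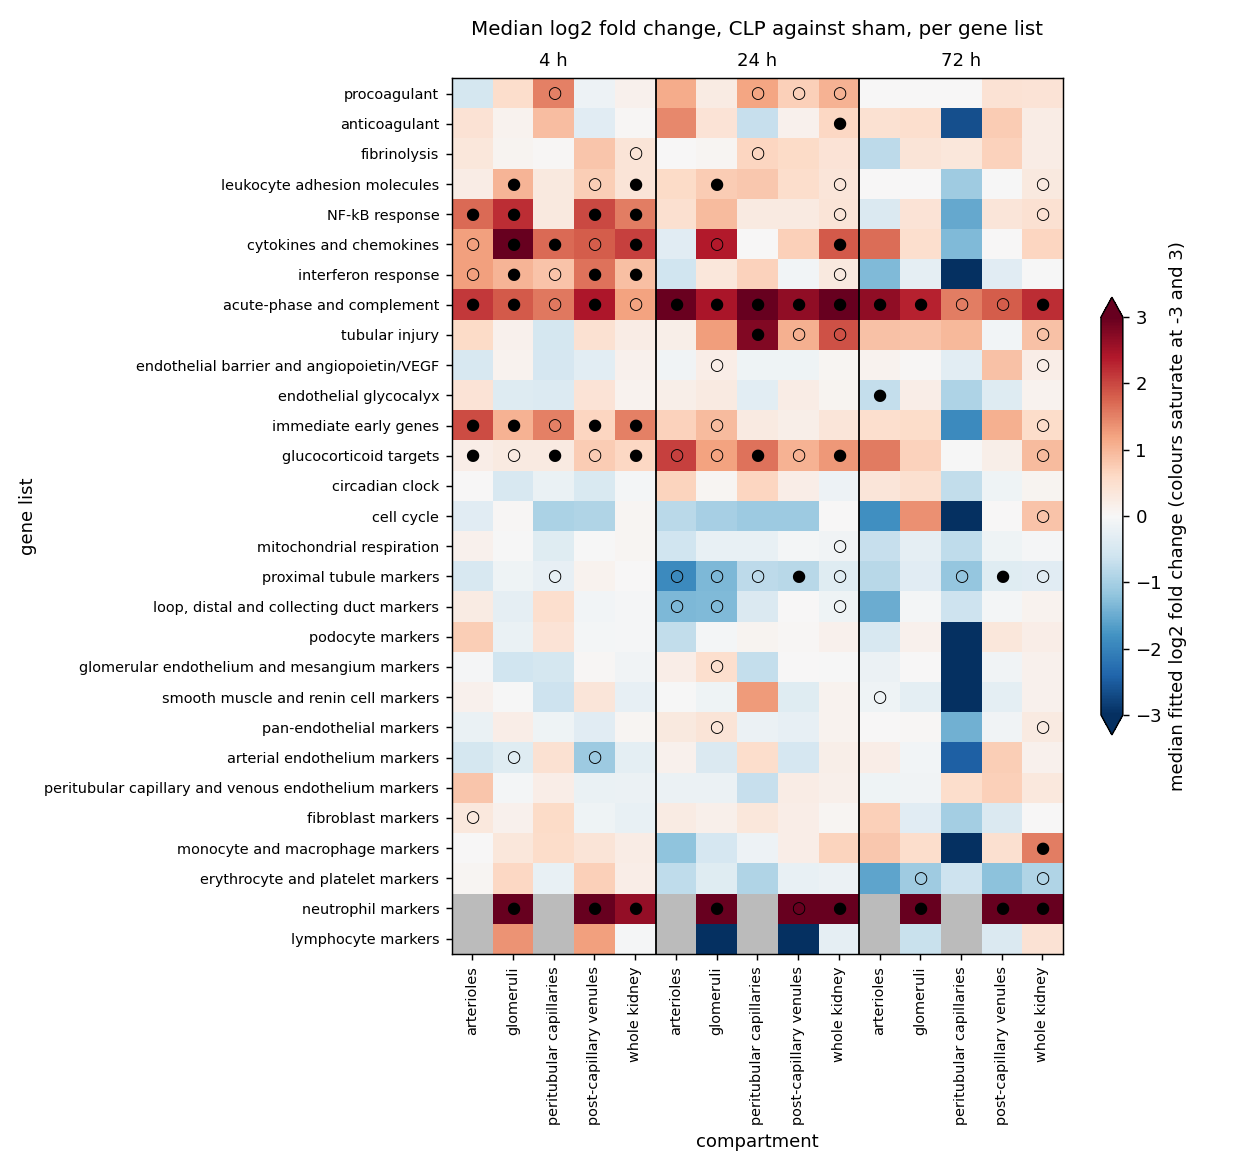
Median fitted log2 fold change, CLP against sham, of each gene list (vertical axis) in each compartment and at each time (horizontal axis), with 4 mice per group and colours that saturate at −3 and 3. Filled circles mark lists called also with an estimated correlation, open circles those called with the preset correlation alone and grey cells lists not tested, and the acute-phase and complement list is called in each of the 15 comparisons.

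At 72 h neutrophil and macrophage markers rose in whole kidney. Erythrocyte and platelet markers (3 of 9 lower) and proximal tubule markers (6 of 18 lower) fell, calls of these 2 lists that were lost with an estimated correlation (adjusted p = 0.25 and 0.11). S100a8 (ENSMUSG00000056054, chromosome 3, 90668978 to 90670035) rose by 6.78 ± 0.46 (adjusted p = 5.55e-10), from 1.72 to 182 CPM, its partner S100a9 by 6.15 ± 0.52, and Ngp was at least 22.4-fold higher. Lyz2 (ENSMUSG00000069516, chromosome 10, 117277331 to 117282321), lysozyme of macrophages and neutrophils, rose by 2.31 ± 0.18 (adjusted p = 1.31e-10), C1qa, a complement gene of macrophages, by 2.22 ± 0.22, C3 by 2.69 ± 0.40 and Saa3 by 8.50 ± 0.90. Kap fell by 1.7 ± 0.12 (adjusted p = 6.73e-11), from 42490 to 13070 CPM, Acsm2 by 0.92 ± 0.12, and Hba-a2, adult alpha globin, by 1.52 ± 0.29. The genes of lowest fold change were the transporters Slc22a7 at −3.14 ± 0.27 and Slco1a1 at −3.03 ± 0.29, and Acsm3 at −3.17 ± 0.24. Proc (ENSMUSG00000024386, chromosome 18, 32123126 to 32139570), protein C of the anticoagulant pathway, fell by 0.86 ± 0.18 (adjusted p = 0.00268), and Serpinf2 by 1.78 ± 0.17. F13a1 passed at 1.60 ± 0.39, lost without sham replicates 2 or 3 or CLP replicate 2 (adjusted p up to 0.0586). Of 14936 genes 260 were higher and 321 lower, and 1214 passed when the 8 libraries alone were fitted with the replicate number as a block (572 without the block). Between 24 and 72 h, 279 genes were called in the same direction and 3 in opposite directions.

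In glomeruli at 72 h, 2 genes rose and 3 fell. Ngp was at least 506-fold higher (adjusted p = 0.000133), with 180 ± 42.8 CPM in CLP mice. S100a8 rose by 6.83 ± 1.06 (adjusted p = 0.00906), from 24.8 to 2828 CPM, lost without sham replicates 1 or 2 (adjusted p up to 0.0682). Hba-a2 fell by 2.06 ± 0.33 (adjusted p = 0.00244), Hbb-bt by 1.89 ± 0.35, lost without sham replicates 1, 2 or 3 or CLP replicate 1 (up to 0.0766), and Hba-a1 by 1.54 ± 0.31, lost without sham replicates 1, 2 or 3 or any of the 4 CLP mice (up to 0.158). The 5 genes became 2 without sham replicates 1 or 2 and 8 without sham replicate 3, and all 5 were called in whole kidney in the same direction.

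In venules at 72 h, 2 genes rose and 4 fell. S100a9 (ENSMUSG00000056071, chromosome 3, 90692632 to 90695721) was at least 307-fold higher (adjusted p = 0.00232), with 82 ± 13.5 CPM in CLP mice, and Inmt (ENSMUSG00000003477, chromosome 6, 55170626 to 55175043), an amine methyltransferase, fell by 2.49 ± 0.41 (adjusted p = 0.000859). Kap fell by 1.5 ± 0.27, lost without sham replicates 1, 2 or 3 or CLP replicates 1, 3 or 4 (adjusted p up to 0.188). Acsm3 was at least 129-fold lower, lost without sham replicate 1 (0.0508), and Ddx54 at least 129-fold higher, lost without any of the 4 sham mice or CLP replicate 3 (up to 0.142). Acy3 fell by 1.15 ± 0.24 (adjusted p = 0.0341), lost without sham replicates 1, 2 or 3 or CLP replicates 1 or 2 (up to 0.188). The 6 genes became 3 without sham replicates 2 or 3 and 12 without sham replicate 4. In edgeR 0 genes passed when fitted to the 8 libraries alone, without or with the replicate number as a block, or to the mice of the same block, so that S100a9 and Inmt also lost their calls (adjusted p up to 0.491 for each). DESeq2 called 1216 genes (1715 had an unadjusted p under 0.05 in edgeR).

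In peritubular capillaries at 72 h, the comparison in which CLP libraries detected the fewest genes, 212 genes were higher and 2413 lower of 11772, and 2276 of these were at 0 in all libraries of one group. Slc5a2 (ENSMUSG00000030781, chromosome 7, 128265657 to 128272430), the glucose transporter of the proximal tubule, was at least 1020-fold lower (adjusted p = 1.63e-12), at 0 CPM in CLP mice and 360.6 in sham mice. Proximal tubule genes with counts in all 8 libraries fell by less, Slc34a1 by 1.45 ± 0.26 (adjusted p = 4.53e-05), Kap by 1.41 ± 0.27 and Acsm2 by 1.76 ± 0.28. Of 15 all-endothelial markers 3 were lower, a list that did not pass with camera (adjusted p = 0.2) and passed with fry (3e-06). Single genes that were lower included Kdr at −6.16 ± 1.67, Robo4, a receptor of endothelium, at least 104-fold and Rgs5, a pericyte gene, at least 130-fold. These bounds and that of Slc5a2 cover counting error only. In libraries with so few detected genes a transcript missed at capture also gives 0, so the true falls may be smaller. The mean of Lcn2, counted in 2 of 4 CLP mice, was at least 153-fold higher (adjusted p = 0.00914). Of 78 named genes that passed, 21 kept the call without each library in turn. The 2625 genes became 1578, 1602 and 1455 without sham replicates 1, 2 and 4, and 583, 1569, 592 and 683 without CLP replicates 1, 2, 3 and 4, and of those shared with whole kidney 106 had the same direction and 25 the opposite one. Fitted to these 8 libraries alone, edgeR called 13 genes. With DESeq2 size factors the median fold change of all genes moved from −1.28 to −0.90, and 1032 genes passed.

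In arterioles at 72 h, 0 of 12183 genes passed in edgeR (2100 had an unadjusted p under 0.05, and DESeq2 called 1728). Without sham replicates 1, 2 and 3 there were 4, 1 and 1, and without CLP replicates 1, 2, 3 and 4 there were 2, 5, 5 and 2. In the summed compartments, 38 genes rose and 34 fell. S100a8 rose by 6.23 ± 0.76 (adjusted p = 7.04e-05), Mmp8, a collagenase of neutrophils, was at least 503-fold and Ngp at least 748-fold higher, C1qb rose by 2.92 ± 0.55 and Lyz2 by 1.80 ± 0.35. The 72 genes became 31, 46 and 39 without sham replicates 1, 2 and 3.

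Neutrophil markers rose at 72 h in glomeruli (14 of 14 positive, 2 higher, 12 adjusted over the list alone, adjusted p = 8.8e-32), venules (6 of 6 positive, adjusted p = 1.2e-08) and whole kidney (9 of 10 higher, median 5.67, adjusted p = 2.1e-23). At 24 h they rose in glomeruli (13 of 14 positive, adjusted p = 3.8e-11) and whole kidney (7 of 10 higher, adjusted p = 3.1e-12), and in venules at 0.0087, lost with an estimated correlation (adjusted p = 0.11). Monocyte and macrophage markers rose in whole kidney at 72 h (9 of 16 higher and 2 lower, adjusted p = 5.3e-09). Erythrocyte and platelet markers fell at 72 h in glomeruli (3 of 11 lower, adjusted p = 0.029) and whole kidney (3 of 9 lower, adjusted p = 0.0022), lost with an estimated correlation (adjusted p = 0.36 and 0.25). Proximal tubule markers fell at 72 h in venules (1 of 18 lower, median −0.37, adjusted p = 2e-05), and in peritubular capillaries (6 of 18 lower, 0.0071) and whole kidney (6 of 18 lower, 4.9e-09), where the call was lost with an estimated correlation (adjusted p = 0.19 and 0.11). At 4 h they fell in peritubular capillaries (median −0.24, adjusted p = 0.0011, and 0.11 with an estimated correlation). Glucocorticoid targets rose in whole kidney at 72 h (5 of 10 higher, adjusted p = 1.8e-05), with Per1 at 2.31 ± 0.33 and Tsc22d3 at 0.94 ± 0.21, and immediate early genes at 0.011, both lost with an estimated correlation (adjusted p = 0.082 and 0.25). Immediate early genes also rose in glomeruli at 24 h (0.028, and 0.068 with an estimated correlation).

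Of lists of vessel structure few passed with camera. In simulated data camera recovered 0 of 10 lists raised 2-fold in arterioles at 24 h, 0 of 10 in peritubular capillaries, 6 of 10 in venules and 10 of 10 in glomeruli and in whole kidney, so that in the first 2 a list that did not pass is no sign of a small change. Endothelial glycocalyx genes fell in arterioles at 72 h (median −0.71, adjusted p = 0.0069), which held with an estimated correlation. Called with the preset correlation alone were smooth muscle and renin cell markers in arterioles at 72 h (down, adjusted p = 0.013, and 0.18 with an estimated correlation), all-endothelial markers in glomeruli at 24 h (up, 0.0038 and 0.14) and whole kidney at 72 h (up, 0.014 and 0.23), glomerular endothelium and mesangium markers in glomeruli at 24 h (up, 0.027 and 0.33), and endothelial barrier genes in whole kidney at 72 h (up, 0.041 and 0.2). Endothelial barrier genes in glomeruli at 24 h were called up (adjusted p = 0.046, and 0.3 with an estimated correlation) with a median of 0.21 and a mean of −0.26, which differ in sign. Cell cycle genes rose in whole kidney at 72 h (adjusted p = 0.00012, and 0.073 with an estimated correlation) and mitochondrial respiration genes fell there at 24 h (0.049 and 0.46). Circadian clock genes (lowest adjusted p = 0.23), podocyte markers (0.14), markers of peritubular capillary and venous endothelium (0.4) and lymphocyte markers (0.098) did not pass with camera in any of these comparisons, and with fry the circadian and podocyte lists passed in peritubular capillaries at 72 h (adjusted p = 0.00017 and 0.0013). Of 423 tests, 105 passed, 86 up and 19 down, and 48 of them held with an estimated correlation. In the summed compartments 37 of 87 passed and 18 held, among them a fall of lymphocyte markers at 24 h (4 of 10 lower adjusted over the list alone, adjusted p = 0.0027). The depth of the compartments in that sum differed between CLP and sham mice at 24 h.

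**Figure D3:**
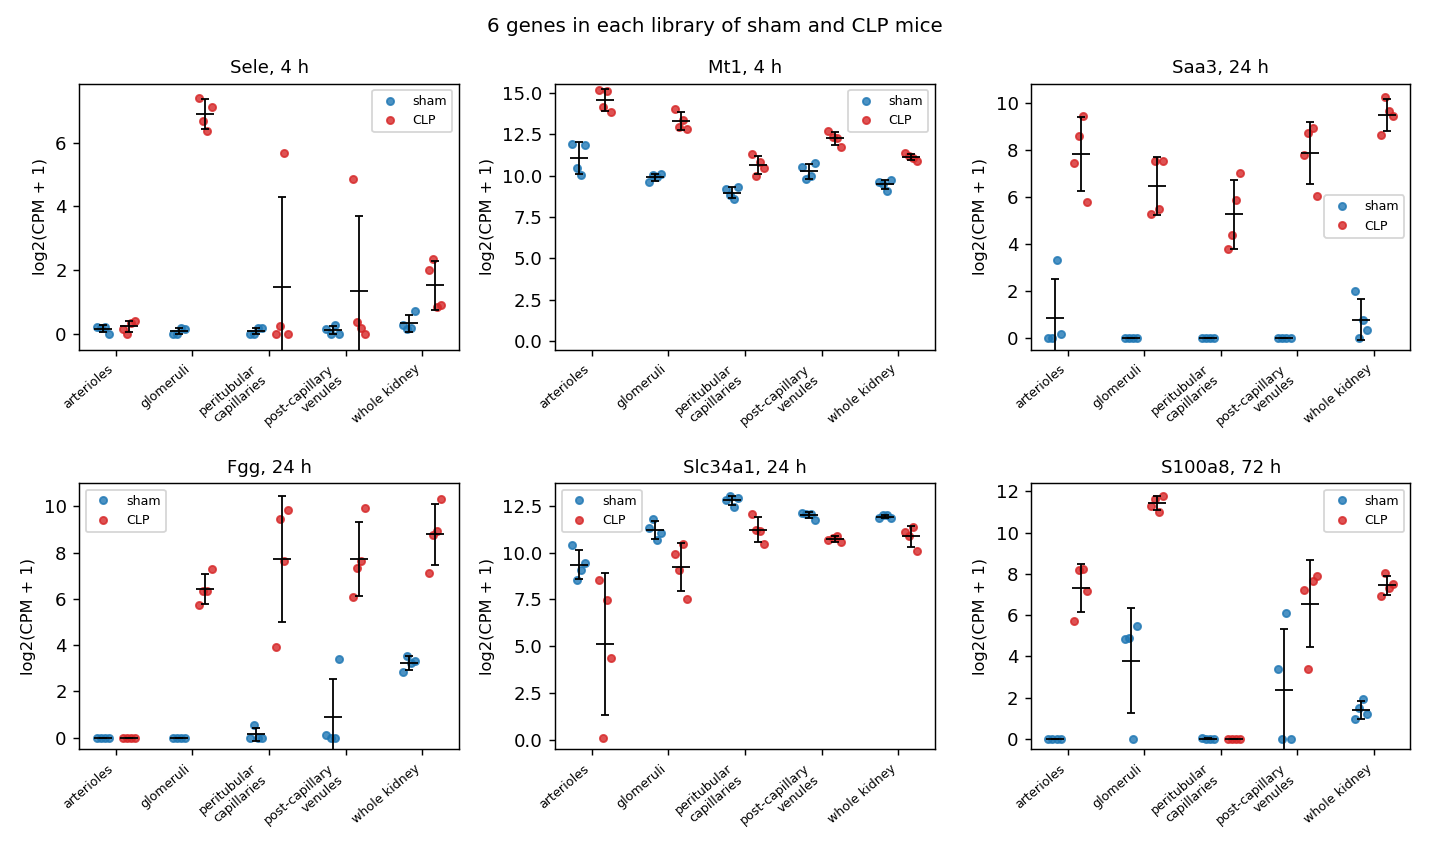
log2(CPM + 1) of 6 genes (vertical axis) in each library, sham in blue and CLP in red, by compartment (horizontal axis), with the mean ± SD of 4 mice, each gene at the time named in its panel. Mt1 at 4 h had 10510 CPM in glomeruli of CLP mice against 963.5 in sham mice, and Fgg at 24 h had 587 against 8.53 in whole kidney.

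Whether the change with CLP differed between the 4 microdissected compartments was tested directly, since a gene that passes in one compartment and not in another need not differ between them. At 4 h 3 genes passed of 14272. Ehd3 (adjusted p = 0.000498) had log2 fold changes of 2.27 in arterioles, −1.41 in glomeruli, −1.25 in peritubular capillaries and −0.77 in venules, and Mt1 (adjusted p = 0.000703) had 3.39, 3.45, 1.71 and 1.98 in that order. Mt1 lost the call without the mouse block (adjusted p = 0.192), and Mt1 and Folr1 lost it without peritubular capillaries (0.0878 for each). Of 21 splits of the mice 5 reached this count of 3, and the highest gave 8. Folr1, a folate receptor of tubules (adjusted p = 0.00799), lost the call without sham replicates 1, 2 or 3 (adjusted p up to 0.14). At 24 h 22 genes passed, among them Serpine2 (adjusted p = 4e-13), Serpinf2 (0.0188) and Lrg1, an acute-phase glycoprotein (0.0136), with fold changes of 3.33, 5.58, 7.11 and 2.54. In simulated data the interaction test at 24 h recovered 0 of 100 genes changed 4-fold and 3 of 100 changed 16-fold. It also called 4 unchanged genes, so single genes called by it at 24 h may be false. At 72 h 200 genes passed, among them Acta2 (adjusted p = 1.08e-27), Kdr (6.4e-05), S100a8 (1.91e-05), Serpine2 (0.000144) and Anxa5, which binds phosphatidylserine (2e-04). Without peritubular capillaries the counts were 1, 7 and 2, and Serpine2 at 24 h and Acta2 at 72 h lost the call. At 4 h the count was 8, 7 and 8 without CLP replicates 1, 2 and 3. At 24 h it was 49, 75, 66 and 57 without sham replicates 1, 2, 3 and 4, and 119, 55, 90 and 57 without CLP replicates 1, 2, 3 and 4. At 72 h it was 101, 120, 80 and 74 without sham replicates 1, 2, 3 and 4, and 315 and 109 without CLP replicates 2 and 3.

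The operation itself was compared with healthy mice at 4 h. In whole kidney Fkbp5 (ENSMUSG00000024222, chromosome 17, 28399094 to 28517527), a target of the glucocorticoid receptor, rose by 2.23 ± 0.24 (adjusted p = 3.95e-06), from 42.2 ± 7.99 to 198 ± 55.8 CPM. In glomeruli the 1 gene called was Tsc22d3 (ENSMUSG00000031431, chromosome X, 140539528 to 140600659), another glucocorticoid target, higher by 2.77 ± 0.41 (adjusted p = 0.000326), at 434 ± 200 against 63.8 ± 3.11 CPM. In the summed compartments 6 genes rose, Tsc22d3 by 2.65 ± 0.38 (adjusted p = 0.000335), Fkbp5, Fkbp10, Ddit4, Per1 and Glul, and 5 of the 6 also rose in whole kidney. These genes and Tsc22d3 in glomeruli were named after their values were seen. Of the 6, Tsc22d3 alone kept the call without each mouse in turn. Fkbp5 lost it without healthy replicates 1, 3 or 4 or sham replicates 1 or 4 (adjusted p up to 0.245), Fkbp10 without any healthy mouse or sham replicates 1 or 4 (up to 0.19), Ddit4 without healthy replicates 1, 2 or 4 or sham replicates 1 or 4 (up to 0.19), Per1 without healthy replicates 1, 3 or 4 or sham replicates 1, 3 or 4 (up to 0.223) and Glul without healthy replicates 1, 2 or 3 or sham replicates 1 or 4 (up to 0.0931). In whole kidney 116 genes were higher and 24 lower of 14936, 140 together, and 67, 73 and 59 without healthy replicate 1, sham replicate 1 and sham replicate 4. In edgeR 0 genes passed in arterioles (668 at an unadjusted p under 0.05, and 226 by DESeq2), 0 in peritubular capillaries (347 and 91) and 0 in venules (644 and 264). Arterioles gave 1 gene without healthy replicate 1, glomeruli 2 without healthy replicate 1 and 4 without sham replicate 3. The summed 6 became 2, 3, 2 and 2 without healthy replicates 1, 2, 3 and 4, and 1 without sham replicates 1 or 4.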

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

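The tests of library complexity in peritubular capillaries, of less dissected tubule and of retained blood were chosen after their results had been seen, as were the summed counts, the interaction without peritubular capillaries and some of the genes whose libraries were compared.

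In peritubular capillaries at 72 h, 2413 genes were lower with CLP in libraries that detected 3961 ± 1178 genes against 8239 ± 1158 in sham mice. A fall of the same genes in the kidney as a whole is argued against by whole kidney at 72 h, where their median log2 fold change was −0.01 (quartiles −0.2 and 0.17) and 90 of 2409 were called lower. Lower complexity of these libraries, from less captured RNA or fewer cells, cannot be told apart from a real loss in these vessels, since each leaves genes without counts, as 87% (2099) of these genes were in all 4 CLP libraries. Lower complexity goes with the share of the 100 most counted genes (48.9 ± 5.14% against 38.9 ± 1.61% in sham mice), with mt-Rnr2 at 11.15 to 22.8% of counts where no gene exceeded 7.694% in sham mice, and with fewer lower genes among 1588 of at least 100 CPM (7.18%) than among the others (22.6%), though a real loss also lowers that mean. For Kap and Acsm2, counted in all 8 libraries, lower complexity is not needed for a fall, since they also fell in whole kidney at 72 h, by 1.7 ± 0.12 and 0.92 ± 0.12, where CLP and sham libraries detected 18324 and 18280 genes, while Slc34a1 (−0.34 ± 0.16 there, adjusted p = 0.324) stays open. The count of 2413 also depends on which libraries were fitted together. Most of these calls were lost when edgeR was fitted to the 8 libraries alone or to the mice of the same block, while DESeq2 called more genes in this comparison. Why the fits differed was not tested.

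Proximal tubule markers were lower at 24 h in each of the 5 compartments. Their precision-weighted mean log2 fold changes were −1.99 ± 0.34 in arterioles, −1.15 ± 0.15 in glomeruli, −0.94 ± 0.11 in peritubular capillaries, −0.70 ± 0.07 in venules and −0.47 ± 0.04 in whole kidney. The ± of these means is an SE that takes the members as independent, so it is too narrow where they move together. With an estimated correlation the call of the list held in venules (adjusted p = 0.04) and not in the other 4 (0.19, 0.19, 0.092 and 0.11). Less tubular tissue dissected with the vessels, as the whole cause, is argued against by whole kidney, which was not microdissected and in which 6 members were called lower and 0 higher in edgeR (1 higher and 7 lower adjusted over the list alone). Less tubule acting on all its transcripts alike is not settled by the summed counts. There 44.4% of the members (8 of 18) lay over 2 SE from their weighted mean of −0.94 ± 0.07, but the sum weights each compartment by its depth. At 24 h arteriole libraries held 10.46 to 13.73 M counts in CLP mice and 6.48 to 10.04 M in sham mice, so the mix of compartments changed too. A smaller share of tubule may still add to the fall in the microdissected libraries, and a response of tubule cells to CLP stays open as a hypothesis, not separated from a loss of these cells.

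Neutrophil genes were higher with CLP in glomeruli, venules and whole kidney. More retained blood of unchanged globin RNA content, as the whole cause, is argued against by glomeruli at 72 h. There the globin gene Hba-a2 had a log2 fold change of −2.06 ± 0.33 while Ngp was at least 506-fold higher. Retained blood with less globin RNA cannot be judged by this gene, which was also at −1.52 ± 0.29 in whole kidney, which was not dissected. The log2 ratio of S100a8 to S100a9 counts in CLP libraries at 72 h was 1.19 in arterioles, 1.17 in glomeruli, 0.96 in venules and 0.86 in whole kidney, a range of 0.34, and in peritubular capillaries there were 0 counts against 492. One kind of leukocyte in every compartment cannot be told apart from several kinds by this ratio, since the 492 counts came from CLP replicate 2 alone (fitted log2 fold change of S100a9 without it 0), and 1 library does not settle a difference. More neutrophils in or on these vessels or in the blood they hold, less globin RNA in that blood, and more S100a8 per cell stay open as biological explanations that were not tested.

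Total counts, detected genes and the share of counts in the 100 most counted genes were compared within each group of 4 libraries, 105 comparisons in all. In 10 of them a library stood apart from the others by Dixon's criterion, which chance meets in about 1 of 20. None of the 10 was in the share of the 100 genes. For total counts these were arterioles of CLP replicate 1 at 24 h (10.46 M counts, lowest) and sham replicate 1 at 4 h (15.61, highest), glomeruli of healthy replicate 3 (9.79, highest) and sham replicate 2 at 24 h (8.01, lowest), peritubular capillaries of sham replicate 1 at 72 h (18.33, highest), venules of CLP replicate 4 at 72 h (13.42, highest) and healthy replicate 3 (4.64, lowest), and whole kidney of CLP replicate 4 at 4 h (16.31, highest). For detected genes they were venules of sham replicate 1 at 24 h (10000, lowest) and whole kidney of CLP replicate 2 at 72 h (19042, highest). In groups of CPM values of single genes, 7 of 120 held such a library, which were Fgg in peritubular capillaries of sham replicate 2 at 24 h (0.476 CPM, highest), Ehd3 in whole kidney of CLP replicate 2 (53.1, highest) and sham replicate 3 (56.4, lowest) at 4 h, Inmt in whole kidney of CLP replicate 3 at 72 h (146, highest), Gm22748 in peritubular capillaries of CLP replicate 1 at 24 h (564, highest), and Per1 in the summed compartments of sham replicate 2 at 4 h (43, lowest) and healthy replicate 2 (26.7, highest).

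In a test of whether the effect of CLP differed between the 4 microdissected compartments, Ehd3 (adjusted p = 0.000498), Mt1 (0.000703) and Folr1 (0.00799) passed at 4 h. Chance was not excluded for this count of 3, which 5 of 21 splits of the mice reached. The highest of the others gave 8 genes. Mt1 and Folr1 lost the call without peritubular capillaries (0.0878 for each), Mt1 without the mouse block (0.192) and Folr1 without sham replicates 1, 2 or 3 (up to 0.14). At 24 h the smallest adjusted p were those of Nat8f1 (4.74e-20), Serpine2 (4e-13), Thnsl2 (2.33e-10), Folr1 (7.84e-08), Pgm1 (4.64e-05), Cd300lg (6.76e-05), Pkia (0.00106), Neurl1b (0.00106), Vim (0.00444) and Gab2 (0.00929). At 72 h they were those of Acta2 (1.08e-27), Rgs5 (1.76e-18), Myh11 (1.79e-14), Ehd3 (3.86e-14), Arpc1b (3.63e-09), Sparcl1 (1.49e-08), Eif3k (1.04e-06), Slc5a2 (1.07e-06), Psmb6 (1.29e-06) and Arhgef17 (1.37e-06). Without peritubular capillaries these 10 genes had an adjusted p of 1, as Serpine2 did at 24 h, while Nat8f1, Thnsl2, Folr1 and Pgm1 stayed past the threshold at 24 h.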

How the results depend on the processing

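The fits to mice of 1 block, to genes with a mean of at least 100 CPM, and without peritubular capillaries, and those of summed counts, were chosen after the results had been seen. No single gene named changed direction under the settings run for it other than leaving out 1 library or mouse. These settings gave from 30 values (interaction without peritubular capillaries) to 593 values (no filter) each. The interaction test has no direction, so its values, among them all of those 30, could not change direction and say nothing on it. Of 3848 values for such genes with 1 library or mouse left out, 2918 kept their side of the threshold, 900 lost and 9 gained it, and 21 reached 0 or changed sign. All 21 were in peritubular capillaries at 72 h. Among the libraries compared there, most counts of the gene came from the library left out, or all of them where the value reached 0. The fitted log2 fold changes of these 21, which depend on the prior count and are no bounds, ranged from −2.36 to 9.75 for Fga, −2.35 to 10.74 for Lrg1, −1.14 to 9.01 for Dusp1, 0 to 10.28 for Alas2, 0 to 12.12 for Arg2, 0 to 10.81 for Fastkd5, 0 to 12.31 for Gcm1, 0 to 12.52 for Krt18, 0 to 12.34 for Lat2, 0 to 10.01 for Plaur, 0 to 10.32 for S100a9, 0 to 11.73 for Saa1, 0 to 12.13 for Sdc1, 0 to 10.87 for Thbs1, 0 to 12.57 for Zbtb16, −11.20 to 0 for Fam187b, −10.86 to 0 for Itgax, −10.23 to 0 for Mx2, −9.40 to 0 for Nphs1, −9.76 to 0 for Plce1 and −12.25 to 0 for Vcam1. In simulated data, of 100 genes changed 4-fold the fit recovered 99 in whole kidney, 12 in glomeruli, 1 in arterioles and 1 in venules at 4 h, and of 100 changed 16-fold it recovered 2 in peritubular capillaries at 4 h, so that in the last 3 changes of these sizes were mostly not detectable at this spread and depth. Unchanged genes called at 4 h were 12 in whole kidney, 2 in venules and 0 in glomeruli, arterioles and peritubular capillaries. No library was below the limit on total counts set for leaving libraries out, so the fit without such libraries gave no values, and the cause of the differences that follow was not tested, except that fewer libraries or fewer genes were used where a setting says so.

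With 1 library left out, or 1 mouse in the summed compartments, the number of genes for CLP against sham ranged at 4, 24 and 72 h from 1 to 2, 1 to 7 and 0 to 5 in arterioles, 4 to 13, 10 to 67 and 2 to 8 in glomeruli, 0 to 0, 2 to 11 and 583 to 2178 in peritubular capillaries, 0 to 2, 4 to 10 and 3 to 12 in venules, 206 to 316, 572 to 1012 and 391 to 573 in whole kidney, and 3 to 17, 45 to 98 and 31 to 87 in the summed compartments. For sham against healthy it ranged from 0 to 1, 1 to 4, 0 to 0, 0 to 0, 59 to 141 and 1 to 7 in that order of compartments. With 1 mouse left out, compartment genes ranged from 608 to 825 in arterioles, 321 to 417 in glomeruli, 455 to 563 in peritubular capillaries and 35 to 44 in venules, and the interaction from 2 to 8, 49 to 119 and 74 to 315 genes at 4, 24 and 72 h.

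Values that moved are given for CLP against sham by time, unless sham against healthy is named, with the count of the text in brackets. DESeq2 called 139, 1522 and 1728 genes in arterioles (1, 2, 0), 303, 986 and 911 in glomeruli (16, 20, 5), 85, 1830 and 4038 in peritubular capillaries (0, 6, 2625), 357, 916 and 1216 in venules (0, 11, 6), and 314, 1230 and 1362 in the summed compartments (14, 91, 72). For sham against healthy DESeq2 called 226 in arterioles (0), 316 in glomeruli (1), 91 in peritubular capillaries (0), 264 in venules (0), 222 in whole kidney (140) and 253 summed (6). DESeq2 called 3307, 1481, 2357 and 761 compartment genes in arterioles, glomeruli, peritubular capillaries and venules (891, 509, 747, 72), and 106, 111 and 665 in the interaction (3, 22, 200).

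Fitted to only the 8 libraries compared, edgeR called 8, 0 and 2 genes in arterioles, 69 and 6 in glomeruli at 4 and 24 h, 4 and 13 in peritubular capillaries at 4 and 72 h, 7, 5 and 0 in venules, 295 in whole kidney at 24 h and 65, 52 and 19 in the summed compartments, and for sham against healthy 1, 3, 1 and 2 in arterioles, glomeruli, peritubular capillaries and venules. Fitted to those 8 libraries with the replicate number as a block, which changes 2 choices, it called 16, 17 and 10 in arterioles, 65 and 9 in glomeruli at 4 and 24 h, 6, 16 and 17 in peritubular capillaries, 20, 6 and 0 in venules, 462 and 1214 in whole kidney at 24 and 72 h (789, 581) and 91, 41 and 5 summed, and for sham against healthy 3, 3 and 3 in arterioles, glomeruli and peritubular capillaries. Libraries of CLP and sham mice with the same number were alike beyond a residual correlation of 0.1 for 3 of 4 pairs in whole kidney at 24 h and 2 at 72 h, and for 0 in the other 13 comparisons, so that in whole kidney the numbers may follow an order of processing. Fitted to mice of the same block, it called 2 and 1 in arterioles at 4 and 24 h, 47, 8 and 2 in glomeruli, 2 and 41 in peritubular capillaries at 4 and 72 h, 6 and 0 in venules at 4 and 72 h and 49, 41 and 27 summed, and for sham against healthy 3, 11, 3 and 6 in arterioles, glomeruli, peritubular capillaries and venules.

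With no filter on low counts it called 6 and 6 in arterioles at 24 and 72 h, 39, 101 and 50 in glomeruli, 650 in peritubular capillaries at 72 h, 4, 21 and 20 in venules, 44, 203 and 243 summed, 8, 2 and 19 for sham against healthy in glomeruli, venules and the sum, and 15 and 61 in the interaction at 4 and 24 h. Among genes with a mean of at least 100 CPM, which are fewer, it called 0 in arterioles at 24 h, 2 and 62 in peritubular capillaries at 24 and 72 h, 2, 17 and 3 in venules, 25, 284 and 214 in whole kidney, 150 summed at 24 h, and 2, 49 and 10 for sham against healthy in glomeruli, whole kidney and the sum. With DESeq2 size factors it called 1032 in peritubular capillaries at 72 h, and the other 30 of 31 counts stayed within 1.5 times. Without the mouse block it called 1420 compartment genes in arterioles and 570 in the interaction at 72 h. Without peritubular capillaries the interaction gave 1, 7 and 2 genes and the sum 51 at 24 h and 32 at 72 h. Of gene lists, 48 passed with an estimated correlation (105 in the text), and in the summed compartments 18, or 23 with fry (37).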

Other observations

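The lists of PPAR-alpha targets and MHC class II genes were written after their genes had been seen to move. The comparison of summed counts was likewise added after the data had been seen.

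In whole kidney at 24 h, targets of PPAR-alpha, the receptor that drives fatty acid oxidation, were higher with CLP. Of 22 measured members 100% had a positive log2 fold change, 14 passed the test, and the median was 1.38 (camera p = 3.1e-24, and 0.00068 with an estimated correlation). Cyp4a14, a fatty acid hydroxylase, rose by 3.53 ± 0.79 (adjusted p = 0.00822), and Pdk4, a kinase that turns pyruvate use down, by 3.50 ± 0.85 (0.0137). At 4 h the list was at p = 0.01 (0.33 with an estimated correlation) and at 72 h lower at 0.028 (0.4). A rise of the list as a whole at 24 h is a hypothesis found in these data, and fasting after the operation, which could also raise these genes, was not recorded in the labels.

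MHC class II genes, which present antigen, were lower in whole kidney at 24 h for 4 of 7 members, with H2-Aa at −1.58 ± 0.15, H2-Eb1 at −1.56, H2-Ab1 at −1.15 and Cd74, the invariant chain, at −0.95, while H2-DMb1, which loads peptides, was higher by 0.82 ± 0.23 (list p = 1.1e-07, and 0.0065 with an estimated correlation). The macrophage genes C1qa, C1qb and C1qc had a median log2 fold change of 1.09. This argues against a loss of antigen presenting cells of every kind only if C1q RNA per cell did not rise. Such a rise could hide a loss of cells and was not tested. A loss of one kind, such as the dendritic cells that express much MHC class II and little C1q, and a lower MHC class II level per cell, may each remain, and neither was tested. At 72 h 3 members were lower (list p = 2.1e-05, and 0.025 with an estimated correlation).

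For 22 of 31 results fewer than 5 in 100 splits of the same libraries gave as many genes, which argues against chance for each taken alone. It does not exclude chance, since with 35 splits, or 21 for the interaction, the real split alone lies near that limit. Excepted are the 3 results of 1 or 2 genes (arterioles at 4 and 24 h, and glomeruli of sham against healthy mice), which passed the highest other split by 1 gene and stay open. The splits were not adjusted over the 31 results. They took no account of the likeness of whole kidney libraries with the same replicate number. Each of the following counts was reached by 1 of 35 splits, the real one, with the highest count of another split after it. With CLP against sham these were arterioles at 4 h (1 gene, 0) and 24 h (2, 1), glomeruli at 4 h (16, 1) and 24 h (20, 5), peritubular capillaries at 24 h (6, 1) and 72 h (2625, 97), venules at 24 h (11, 1) and 72 h (6, 2), whole kidney at 4 h (335, 0), 24 h (789, 111) and 72 h (581, 3), and the summed compartments at 4 h (14, 1), 24 h (91, 2) and 72 h (72, 5). With sham against healthy they were glomeruli (1, 0), whole kidney (140, 1) and the summed compartments (6, 1). Of 100 splits of the healthy libraries by compartment, 1 reached the count for arterioles (891, highest other 380), glomeruli (509, 457) and peritubular capillaries (747, 453), and of 21 splits 1 reached the interaction count at 24 h (22, 16) and 72 h (200, 32). The interaction test at 24 h also called 4 unchanged genes in simulated data, so its split says little on single genes.

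For 6 of the other 9 results the count was 0, which each split reaches, so the splits decide nothing. In arterioles at 72 h (0 genes in edgeR, 2100 at an unadjusted p under 0.05 and 1728 by DESeq2; highest other split 6), arterioles of sham against healthy mice (0, 668 and 226; 0), peritubular capillaries at 4 h (0, 384 and 85; 0) and sham against healthy (0, 347 and 91; 0), and venules at 4 h (0, 768 and 357; 0) and sham against healthy (0, 644 and 264; 1), 35 of 35 splits gave as many. For the remaining 3 the splits do not argue against chance. In glomeruli at 72 h 3 of 35 splits gave at least the 5 genes of the real one, and the highest other gave 28. For compartment genes of venules 6 of 100 splits reached the 72 of the real one, with 185 the highest, and for the interaction at 4 h 5 of 21 reached 3, with 8 the highest. A split with several times the real count, as in glomeruli at 72 h, may come from a structure of the samples other than the groups compared, which was not tested.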
